A study of Oryza sativa with 2 samples.

How the data were processed

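The series holds 2 single-cell RNA libraries of rice root tip protoplasts, 1 from 93-11 (indica) and 1 from Nipponbare (japonica). Per the labels, seedlings grew in nutrient solution for 3 days, the 5 mm tips of 800 crown roots were digested with cell wall enzymes, and 18000 cells were loaded per chip. Libraries were made with the Chromium 3' v2 chemistry and sequenced on an Illumina instrument, per the labels' protocols. That chemistry reads the 3' end of transcripts and tags each captured molecule with a UMI, so that PCR copies are counted once. Transcripts that respond to the enzyme treatment may be part of what was measured, and neither library was made from undigested tissue. The samples were grouped by the cultivar named in their labels.

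The deposited values were raw UMI counts per gene identifier and cell barcode, made with Cell Ranger 2.2.0 per the submitters' processing notes. The matrices contained called cells only, with at least 3234 UMIs per barcode in 93-11 and 4442 in Nipponbare. The genome builds and annotations are not given in the sources used here. The 93-11 file listed 38501 identifiers and the Nipponbare file 39217, of which 34407 occurred in both. Most were of the LOC_Os form (38011 and 38922), and 490 and 295 were of the EVM form. The libraries were thus counted against different lists, and a gene model that differs between them changes the count of its identifier. Only identifiers on both lists were compared between cultivars. The remaining 4094 identifiers of 93-11 and 4810 of Nipponbare stayed in the library totals and in the clustering of their own library. No coordinates are printed. A total of 189 barcodes occurred in both libraries, and cells were kept apart by library.

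Cells with at least 500 genes were kept, which removed none. Doublets were scored with scrublet in scanpy 1.11.5 at an expected rate of 8%. Its automatic threshold marked 2 cells in each library (0.0159% and 0.0182%) and so had not worked. A score above 0.25, set after the scores were seen, was used instead. It removed 418 barcodes of 93-11 (3.33%) and 354 of Nipponbare (3.23%), with median depths of 10131.5 and 9904.5 UMIs, against 8514 and 8374.5 in the other barcodes. That score was exceeded by 34.9% and 37.1% of the simulated doublets, so a part of the doublets remained. No correction for free RNA was made.

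Each library was clustered on its own. UMI counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken by dispersion within 20 bins of mean level. These were scaled, limited to 10 SD and reduced to 30 principal components. A graph of shared nearest neighbours (15 neighbours, Jaccard weight of at least 0.067) was divided with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Clusters are numbered by size. Leading identifiers of a cluster had the largest fold over the other cells of the library among those seen in at least 10% of the cells of the cluster. These folds were formed on UMIs per 1000000 UMIs plus 1. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals.

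Cell type markers and function lists, 123 identifiers in 18 lists, were fixed before the data were examined, in the Os-number form of the rice annotation project. None of them occurred in the files, and neither these nor the 43311 identifiers of the files were found in the RefSeq gene table, so no list could be joined to the counts. The plan to compare named cell classes was therefore replaced, after the files were seen, by pairs of clusters. Profiles were log2 of UMIs per 1000000 UMIs (UPM) plus 10, centred per identifier over the clusters of a library, for 12917 identifiers with at least 100 UMIs in each library. A 93-11 cluster and a Nipponbare cluster formed a pair where each was the other's highest Pearson correlation.

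For the comparison over all cells, UMI counts were summed over the kept cells of each library (111171626 in 93-11 and 107675584 in Nipponbare) and divided by the library total. Ratios carry exact conditional binomial 95% intervals, which cover counting error only. Identifiers with at least 100 UMIs in 1 library entered the summaries, as log2 of UPM plus 1. The naming rule took the 10 largest ratios in each direction over all cells and the 5 largest in each direction within a pair, among identifiers with at least 100 UMIs in 1 of the sums and at least 1 in the other. Identifiers with no UMI in one library were listed apart, with the bound from 3 counts per library. As the files give no gene names, at most 2 identifiers per direction are printed for each comparison. Within pairs, ratios were formed from cluster sums as log2 of UPM plus 10 for identifiers with at least 100 UMIs over both clusters. With 1 library per cultivar no test of a difference was run and no p-value is given. Numbers of identifiers past a size of ratio describe these 2 libraries and are not numbers of changed genes.

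The ratio step was tested on simulated data for 93-11 against Nipponbare over all cells. Among 94 identifiers changed 2-fold the median recovered fold was 1.995 and 95.7% of the intervals held the true value. Among 106 changed 4-fold these values were 4.017 and 95.3%, and among 14495 unchanged ones 95.6% of the intervals held a ratio of 1. The library totals were simulated with counting error alone, which is what the intervals assume, and no cells were drawn. Coverage near 95% was therefore built in, so the result checks the calculation only. The clustering and matching steps were tested on 12 simulated clusters of 120 cells per library, and all 12 were found and paired correctly. Both simulated libraries were drawn from the same Nipponbare profiles. The second carried a log2 effect of SD 1 per identifier that was the same in every cluster. Centring per identifier largely removes such an effect, and cluster sizes were equal. The result therefore does not show that the pairs found in the data are correct. Alternatives varied the resolution, variable genes, components, doublet removal, scaling, weighting of cells and depth. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.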

Results

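Single-cell transcriptomes were collected from rice root tips of 2 cultivars, 93-11, an indica cultivar, and Nipponbare, a japonica cultivar. Protoplasts, which are plant cells freed of their walls by enzymes, were prepared from the 5 mm tips of crown roots of 3-day-old seedlings. Each cultivar gave 1 droplet library (10x Chromium 3' chemistry), so no comparison between the cultivars has a replicate. The measurement was the number of UMIs, the molecular tags that mark single captured transcripts, per gene identifier and cell barcode. Values of the 2 libraries are therefore set side by side with no test, and all intervals are exact 95% intervals that cover counting error only. A difference between the libraries cannot be separated from a difference between plants, protoplast preparations or runs.

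The 93-11 library held 12564 barcodes with 115739478 UMIs, and the Nipponbare library held 10968 barcodes with 111598192 UMIs. Every barcode passed the minimum of 500 genes: the poorest one had 1067 genes in 93-11 and 1329 in Nipponbare. After removal of 418 and 354 putative doublets, 12146 cells of 93-11 and 10614 cells of Nipponbare were kept. The median kept cell of 93-11 had 8514 UMIs (interquartile range 6458 to 10854) and 2624 genes. In Nipponbare the median kept cell had 8374.5 UMIs (interquartile range 6548 to 11494) and 2580 genes. Over all barcodes, no identifier took a large part of either library. The most abundant was LOC_Os08g10480 in 93-11, with 0.956% of the UMIs, and LOC_Os02g44310 in Nipponbare, with 0.961%. The 20 most abundant identifiers held 10.2% of the UMIs of 93-11 and 9.57% of those of Nipponbare.

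The first question was which groups of cells the root tips held and whether both cultivars contained matching ones. Clustered separately, the cells of 93-11 fell into 22 clusters and those of Nipponbare into 19. Of these, 14 clusters of 93-11 and 14 of Nipponbare were each other's best match by their expression profiles, and these pairs held 70.0% of the 93-11 cells and 69.8% of the Nipponbare cells. This share depended on the settings, from 58.8% to 78.8% in 93-11 and from 60.0% to 95.9% in Nipponbare, with the highest values at resolution 0.5. The closest matches were 93-11 cluster 13 with Nipponbare cluster 16, with a Pearson correlation across identifiers of 0.881, and 93-11 cluster 15 with Nipponbare cluster 12, with 0.878. The median over the 14 pairs was 0.760. The clusters carry numbers and not names, because the deposited identifiers could not be joined to those of the cell type markers. Genes are not independent replicates, so these correlations describe profiles and carry no p-value.

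The identifiers that led a cluster describe it and are not results of a test. Their folds were taken on UMIs per 1000000 UMIs plus 1, which shrinks the fold of an identifier scarce in the other cells. LOC_Os05g04500 led 93-11 cluster 9, where its level was 101-fold that of the other cells, and also Nipponbare cluster 1, where it was 107-fold. Overlap was taken among the first 20 leading identifiers of each cluster that were on the identifier lists of both libraries. The pair of 93-11 cluster 9 and Nipponbare cluster 1 shared 13 of these 20, and the pair of 93-11 cluster 16 with Nipponbare cluster 18 shared 12. Cluster 21 of 93-11 and cluster 19 of Nipponbare shared 11, although they held only 35 and 20 cells. LOC_Os07g01370 was 1623-fold and 1945-fold above the other cells in these small clusters. LOC_Os04g34630 led both members of the pair of 93-11 cluster 15 and Nipponbare cluster 12, at 228-fold and 402-fold. At the other end, 93-11 cluster 2 and Nipponbare cluster 4 shared none of the 20 while their profiles correlated at 0.755.

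Some matches were less distinct than others. Cluster 8 of 93-11 correlated at 0.789 with Nipponbare cluster 14 and nearly as well, at 0.725, with Nipponbare cluster 6. Cluster 4 of 93-11 correlated at 0.613 with Nipponbare cluster 11 and at 0.580 with Nipponbare cluster 8, a smaller gap. In 93-11, 8 clusters had no reciprocal partner, and in Nipponbare 5 had none. The largest was 93-11 cluster 3, with 1345 cells, or 11.1% of its library, whose best match reached only 0.417. Cluster 11 of 93-11 reached 0.391 and was shallow, with a median of 5165 UMIs per cell. However, 93-11 cluster 16 was shallower, with a median of 4816.5, and had a partner at 0.595. The best unpaired match was that of 93-11 cluster 20, with 36 cells, which correlated at 0.753 with Nipponbare cluster 16. With 1 library per cultivar, a cluster without a partner was not taken as a cell group that the other cultivar lacked.

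**Figure D1:**
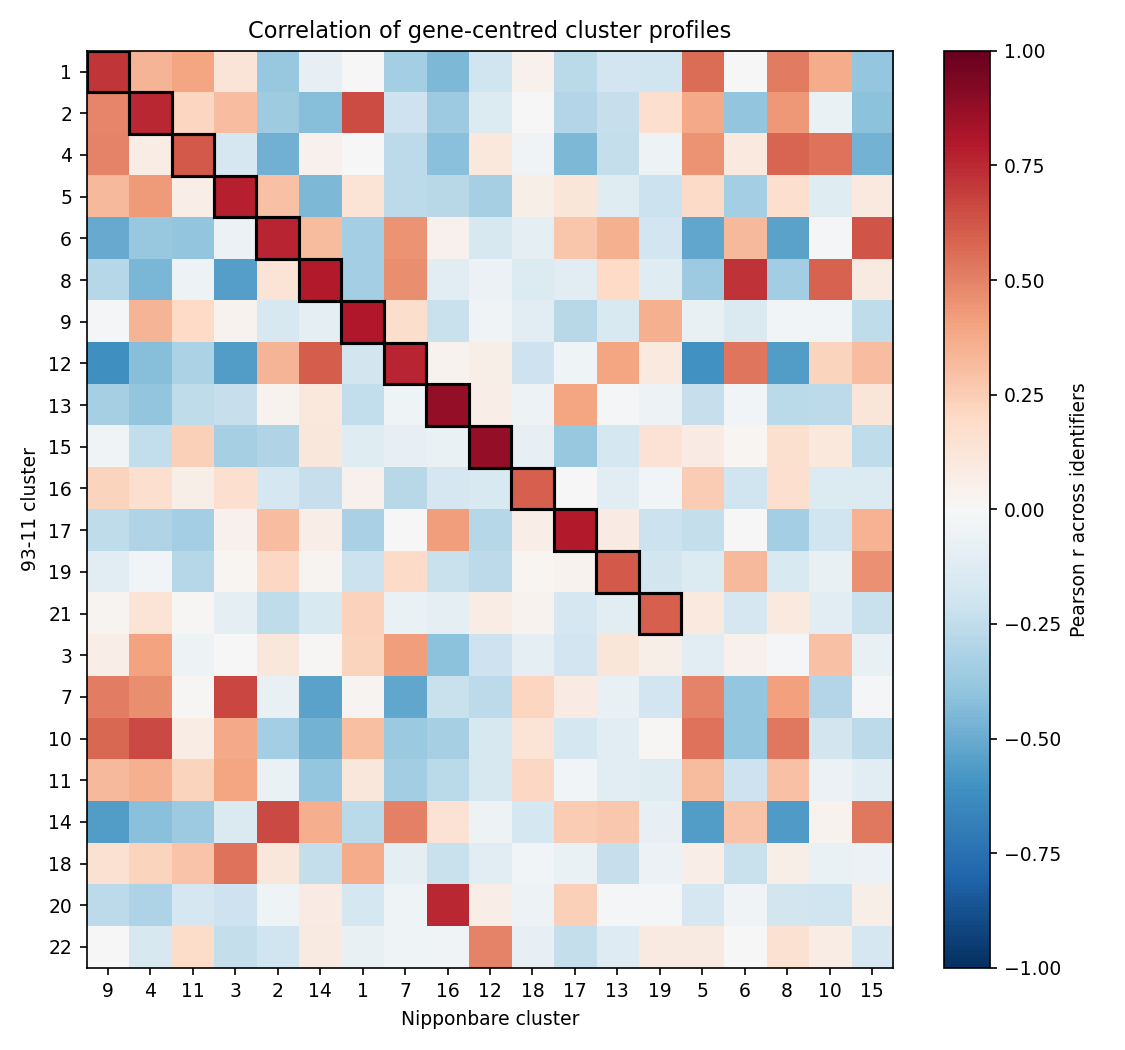
Pearson correlation across 12917 identifiers between each 93-11 cluster (vertical axis) and each Nipponbare cluster (horizontal axis), from gene-centred log2 profiles, with red for positive and blue for negative values. The 14 outlined reciprocal pairs lie between 0.595 and 0.881.

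Within 93-11 the largest cluster, cluster 1, held 12.01% of the cells (11.4% to 12.6%). Its Nipponbare partner, cluster 9, held 6.98% (6.504% to 7.48%). With the cells of both libraries assigned to the 93-11 clusters, the order of this pair turned, with 9.88% of the 93-11 cells and 10.8% of the Nipponbare cells in cluster 1. On the Nipponbare clusters the order stayed, with 7.96% of the 93-11 cells and 7.03% of the Nipponbare cells in cluster 9. In Nipponbare the largest was cluster 1, with 11.6% (11.0% to 12.2%), whose 93-11 partner, cluster 9, held 4.84% (4.47% to 5.24%). This 2.39-fold gap fell to 1.23-fold with the cells of both libraries assigned to the Nipponbare clusters and to 1.57-fold on the 93-11 clusters. Cluster 13 of 93-11 held 2.78% (2.50% to 3.09%) and Nipponbare cluster 16 held 1.25% (1.05% to 1.48%). Cluster 15 of 93-11 held 1.88% (1.64% to 2.13%) and Nipponbare cluster 12 held 4.06% (3.69% to 4.45%). Cluster 17 held 1.24% (1.05% to 1.46%) in 93-11 and 1.11% (0.921% to 1.33%) in Nipponbare, with overlapping intervals. Each library was divided on its own and partners differed in part of their leading identifiers, so these are shares of clusters within a library, and no change of a cell type was read from them.

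**Figure D2:**
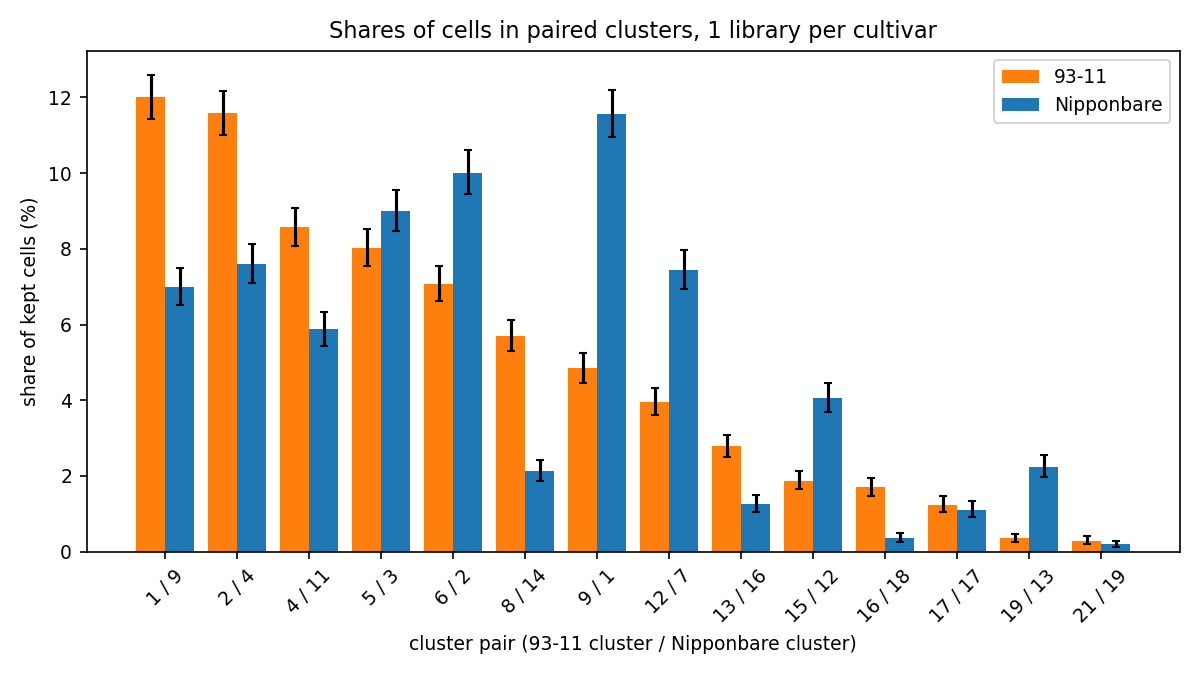
Share of kept cells (percent) in each of the 14 pairs of clusters, for 93-11 (orange) and Nipponbare (blue), with error bars for exact binomial 95% intervals of counting error in 1 library per cultivar. The shares run from 0.288% to 12.01% in 93-11 and from 0.188% to 11.6% in Nipponbare.

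The second question was how far the same identifiers differed between the cultivars over all kept cells. Several were abundant in one library and close to absent from the other. LOC_Os10g28170 had 711114 UMIs in 93-11, or 6396.5 per 1000000 UMIs of the library (UPM), and 29 UMIs in Nipponbare, or 0.269 UPM, a 23750-fold higher level in 93-11 (16537 to 35463). LOC_Os11g06340 had 41931 UMIs (377 UPM) in 93-11 and 1 UMI in Nipponbare, a ratio of 40612 with an interval from 7289 to 1.60e+06. In the opposite direction, LOC_Os01g60410 had 6 UMIs in 93-11 and 55520 UMIs (516 UPM) in Nipponbare, 9554-fold higher there (4389 to 26034). LOC_Os11g47574 had 1 UMI in 93-11 and 19041 UMIs (177 UPM) in Nipponbare, a ratio of 19659 with an interval from 3528 to 776540. These 4 had the largest ratios of their direction among identifiers counted in both libraries. The files do not pair identifiers with gene names, so only these are printed.

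UMIs of these 4 identifiers were found in every cluster of the library where they were abundant. Free RNA, which can carry UMIs into all cells of a library, was not measured, so a UMI in a cluster was not read as expression there. LOC_Os10g28170 ranged from 3040 UPM in 93-11 cluster 18 to 10267 in cluster 7, and LOC_Os11g06340 from 74.99 in cluster 11 to 566 in cluster 17. In Nipponbare, LOC_Os01g60410 ranged from 338 UPM in cluster 8 to 867 in cluster 16, and LOC_Os11g47574 from 33.3 in cluster 16 to 329 in cluster 4.

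A further 104 identifiers on both lists had at least 100 UMIs in 93-11 and none in Nipponbare. They held 229233 UMIs, or 0.206% of the 93-11 library. Another 162 had at least 100 UMIs in Nipponbare and none in 93-11, with 213592 UMIs, or 0.198% of that library. The most abundant one in 93-11 had 51991 UMIs, at least 16785-fold higher than the limit that 3 counts set for Nipponbare. The most abundant one in Nipponbare had 46885 UMIs, at least 16136-fold higher than the same limit for 93-11. The 2 libraries were deposited with different identifier lists, of 38501 and 39217 entries with 34407 in common, and whether a shared identifier covers the same stretch of sequence in both is not given in the sources used here.

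Most identifiers differed far less. Across the 16118 identifiers with at least 100 UMIs in 1 library, log2 levels of the libraries correlated at a Pearson r of 0.830 and a Spearman rho of 0.790. The log2 ratio of 93-11 over Nipponbare had a median of -0.12 and an SD of 1.35 across identifiers, with 10th and 90th percentiles of -1.55 and 1.31. Random division of the cells of 1 library into equal parts gave an r of 0.998 and an SD of 0.145 in 93-11, and 0.999 and 0.112 in Nipponbare. The difference between the libraries was thus larger than the sampling of cells within a library. No spread between plants or libraries of 1 cultivar was measured.

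**Figure D3:**
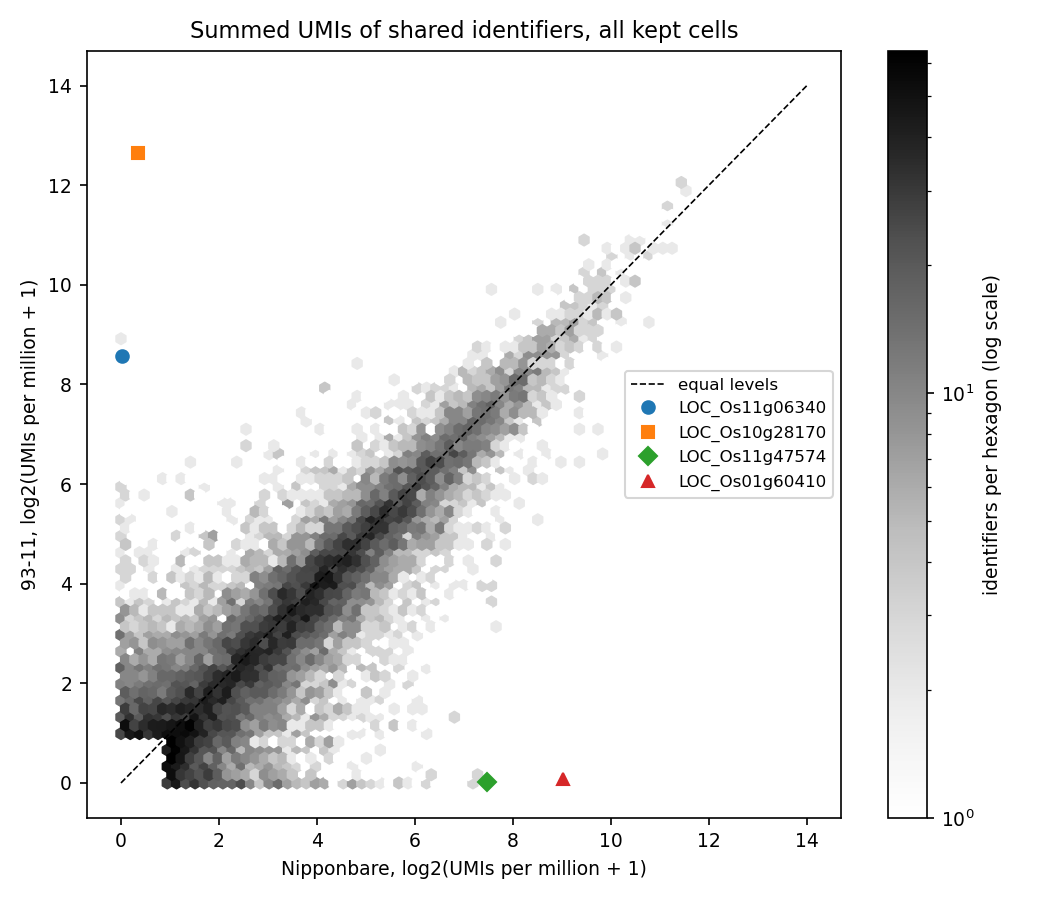
Summed UMIs of 93-11 (vertical axis) against Nipponbare (horizontal axis), both as log2 of UPM plus 1, for identifiers on both lists, with darker hexagons holding more identifiers on a log scale and the dashed line marking equal levels. LOC_Os10g28170 (6396.5 against 0.269 UPM) and LOC_Os11g06340 lie at the upper left, and LOC_Os01g60410 (0.054 against 516) and LOC_Os11g47574 at the lower right.

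The third question was whether the cultivars also differed within matching cells. LOC_Os10g28170, LOC_Os11g06340, LOC_Os01g60410 and LOC_Os11g47574 kept the direction seen over all cells in each of the 14 pairs of clusters. They were chosen for their ratios over all cells and were close to absent from one library. Their direction in a pair could therefore hardly turn and does not answer the question. LOC_Os11g47574 was sparser than LOC_Os01g60410, with 14 to 86 UMIs in 4 of the paired Nipponbare clusters. LOC_Os10g28170 had between 1810 and 96692 UMIs in each of the 14 paired 93-11 clusters and at most 9 UMIs in any paired Nipponbare cluster. LOC_Os01g60410 had between 100 and 7763 UMIs in each paired Nipponbare cluster and at most 1 UMI in any paired 93-11 cluster. Beyond these, LOC_Os04g46820 was among the 5 largest ratios toward 93-11 in 7 of the 14 pairs, at 125-fold to 1362-fold in those pairs. Its ratio depended on the cluster: its log2 ratio over all cells was 6.45, and outside the pair of 93-11 cluster 1 and Nipponbare cluster 9, where it was 793-fold, it was 70.4-fold. LOC_Os11g10520 was among the 5 largest toward Nipponbare in 8 pairs, at 627-fold to 5241-fold in those pairs, and LOC_Os07g37100 in 6 pairs, at 264-fold to 4106-fold. Only identifiers with at least 1 UMI in both clusters were ranked, so these numbers of pairs do not count where a difference occurred. On UPM plus 10, LOC_Os11g10520 had a median log2 ratio of -7.40 over 14 pairs, and LOC_Os07g37100 had -5.08 over 13.

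**Figure D4:**
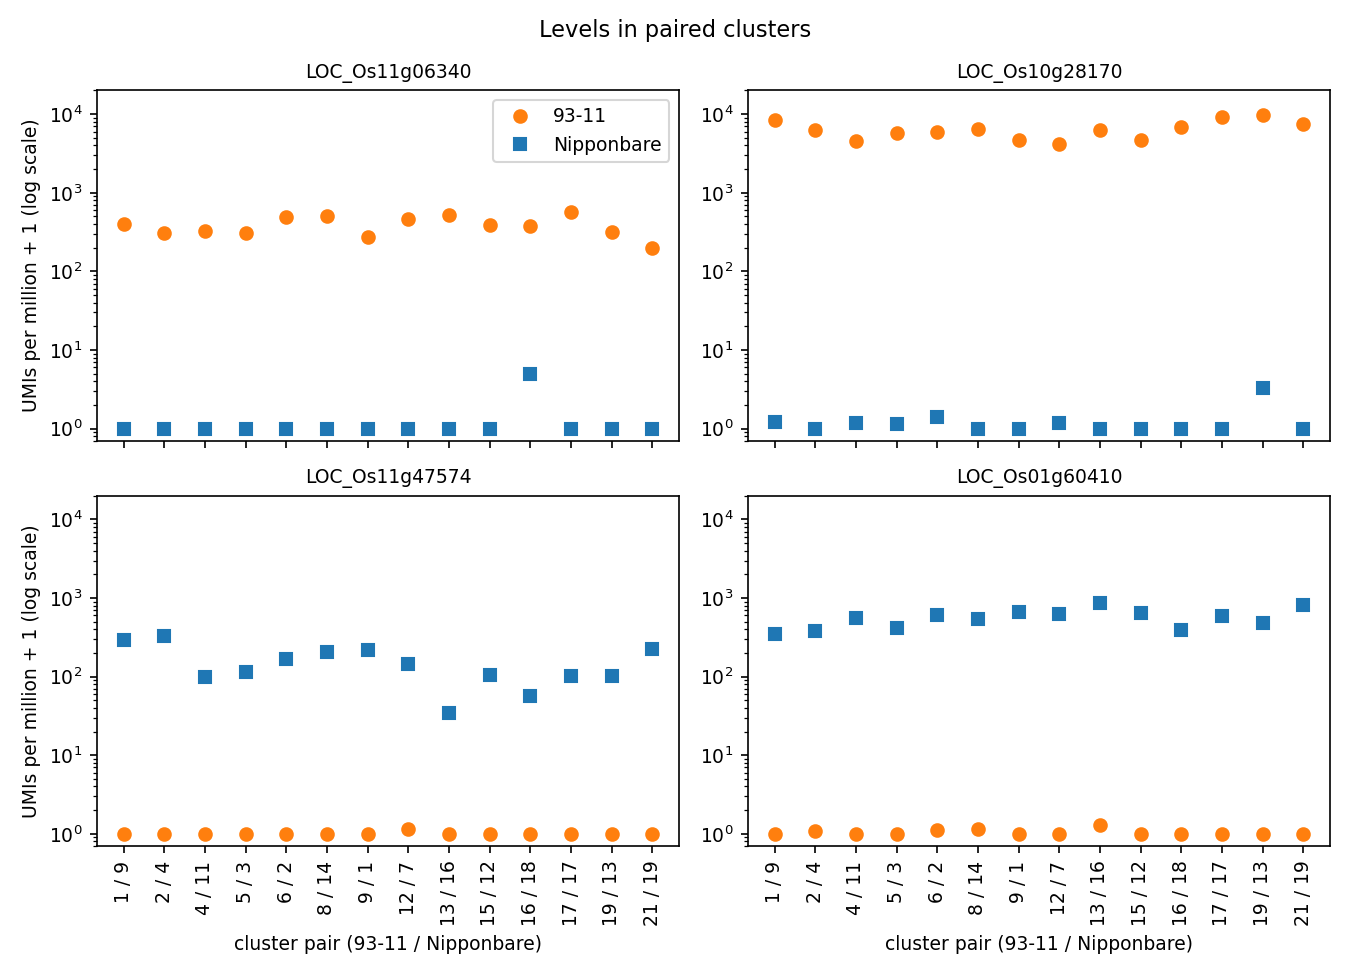
UPM plus 1, on a log axis, of 4 identifiers in the 14 pairs of clusters, with 93-11 as orange circles and Nipponbare as blue squares. LOC_Os10g28170 lies between 4199 and 9786 UPM in every paired 93-11 cluster and at 2.29 or less in every paired Nipponbare cluster.

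The log2 ratios of different cluster pairs, taken on UPM plus 10, which shrinks the ratios of low identifiers, resembled each other. Over the 91 combinations of 2 pairs, their correlation across identifiers had a median of 0.790 (range 0.654 to 0.920). All pairs came from the same 2 libraries, so any effect on a whole library enters every pair and these combinations are not independent. For the 4937 identifiers compared in at least 10 pairs, 81.3% of the variance of the log2 ratio lay between identifiers, and the remainder between pairs of the same identifier, counting error included. The ratio of a single identifier varied across pairs with a median SD of 0.42, against an SD of 1.04 across identifiers of their median ratio. The sums of the smallest pair, 93-11 cluster 21 and Nipponbare cluster 19, held 241464 and 213182 UMIs and allowed only 863 identifiers to be compared, against 9620 in the pair of 93-11 cluster 6 and Nipponbare cluster 2.

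The fourth question, which clusters carried the genes of aquaporins, iron acquisition, low oxygen response and the other lists fixed before the data were examined, was not answered. None of the 123 listed identifiers occurred in the files, and neither they nor the 43311 identifiers of the files occurred in the reference table. No level is therefore given for any of these lists.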

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

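No test was run for the values in this part, and the thresholds that selected them were set after the data were seen. An identifier was taken where it was enriched in one member of a pair of clusters and depleted in the other, each against the remaining cells of its own library, with at least 1000 UMIs in each library. Enrichment and depletion were taken on UPM plus 10, which shrinks the values of low identifiers. There were 40 combinations of an identifier and a pair in which both values were at least 2-fold on this scale. The 4 strongest follow, each with the smaller size of its opposite values.

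LOC_Os05g49260 fell by 1.83 on the log2 scale in 93-11 cluster 13 and rose by 2.34 in Nipponbare cluster 16, from 45 and 731 UMIs, with a smaller size of 1.831. LOC_Os02g52430 fell by 1.61 in 93-11 cluster 13 and rose by 1.83 in Nipponbare cluster 16, from 335 and 932 UMIs, with a smaller size of 1.611. In the same pair of clusters LOC_Os07g34720 rose by 1.56 in 93-11 and fell by 2.24 in Nipponbare, from 157 and 16 UMIs, with a smaller size of 1.555. LOC_Os08g35110 rose by 2.29 in 93-11 cluster 19 and fell by 1.72 in Nipponbare cluster 13, from 482 and 181 UMIs, with a smaller size of 1.723. The difference was not tested for any of these 4, since each cultivar had 1 library, and the clusters of the last pair held 43 and 238 cells. Partners may also hold different cells. Nipponbare cluster 16 correlated at 0.753 with 93-11 cluster 20 as well. Of the 93-11 cells assigned to Nipponbare cluster 13, only 22.7% came from 93-11 cluster 19.

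Some of the signal lay on identifiers that only one file lists and that no comparison between the cultivars used. These held 3.995% of the UMIs of 93-11 and 3.265% of those of Nipponbare, far above the limit that 3 counts set. The most abundant of them was LOC_Os02g48710 in 93-11, with 390709 UMIs, and EVM0012725 in Nipponbare, with 391658 UMIs and at least 1 UMI in 100% of the cells.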

How the results depend on the processing

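The doublet score of 0.25, its alternative (the automatic threshold) and the use of cluster pairs in place of named classes were chosen after the data were seen. The 20 named identifiers were chosen for their extreme ratios, so that their direction could hardly turn and says nothing about stability. Clusters in Nipponbare rose from 19 to 31 at resolution 2, as that setting is made to divide more finely, and 93-11 then had 31. The other settings gave 15 to 22 clusters in 93-11, 14 to 22 in Nipponbare and, with resolution 2 included, 12 to 19 pairs. Cells were reassigned more than these counts show, with an adjusted Rand index of 0.554 to 0.788 against the reported clusters. The Pearson r between the libraries was 0.8326 with every cell weighted alike and 0.7439 with every cell thinned to 2000 UMIs. Thinning also raised the SD of the log2 ratio to 1.4982, with 11416 in place of 16118 identifiers above the count minimum. The cause of these changes was not tested. Median-of-ratios and TMM scaling shifted all log2 ratios by a constant and left r and SD as they were, and with doublets kept r was 0.831. Use of all deposited barcodes is the same set of cells as doublets kept. The median correlation of ratios between cluster pairs was 0.7907 to 0.7997 under its 4 alternatives. The gene minimum of 0 or 1000 removed no cell and shows nothing. Allowing list members among the variable genes, a minimum of 10 UMIs for list members, and all alternatives of the function lists were not run, because no list member could be joined to the files. No paired analysis was possible because each cultivar had 1 library and no test was made. Depth limits the small clusters most: the pair of 35 and 20 cells allowed 863 identifiers to be compared.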

Other observations

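The comparison of adjacent identifiers with random places and the tests of the single pairs of clusters were chosen only after the results were seen. The other tests had bounds set before their results were seen. For the mix of cells and for the shares of the set of pairs, further conditions that were not part of those bounds left the outcome undecided. The identifiers named in the next paragraph were chosen after their values were seen.

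LOC_Os04g27860 differed between the cultivars more in one pair of clusters than in the remaining cells. In the pair of 93-11 cluster 15 and Nipponbare cluster 12 it had 21 against 5427 UMIs, 112-fold higher in Nipponbare (73.5 to 182, counting error only), and in the remaining cells 825 against 3571 UMIs, 4.64-fold higher (4.30 to 5.01). Its level in 93-11 was 7.33 UPM in cluster 15 and 7.62 in the remaining cells, while in Nipponbare it was 823 UPM in cluster 12 and 35.3 in the remaining cells. LOC_Os01g48770 was concentrated in the same 93-11 cluster, at 2446 UPM against 69.9 in the remaining cells, and had 3 UMIs in all of Nipponbare. Its ratio between the cultivars was 8063 (2231 to 66590) in this pair and 7061 (1267 to 278900) in the remaining cells, which were not distinguishable at this depth.

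A total of 836 identifiers were over 32-fold apart between the libraries, with a UMI count under 3 set to 3, 486 lower in 93-11 and 350 lower in Nipponbare. A different mix of cells stays open: the 472 that could be compared inside pairs of clusters had a median log2 ratio of 5.603 there, past the bound of 3 set beforehand, but the minimum of 100 UMIs favoured that outcome, 364 could not be compared, and free RNA was not measured. Reads counted on an adjacent identifier in the other library would need a matching excess at a neighbour, and 39.71% had one, between the bounds of 10% and 50% set beforehand. Random places gave a median of 40.1% and a highest value of 43.2% in 100 draws, so the lower bound could not have been met. The ratio of 0.991 to that median gave no excess over chance. As random places passed this often, misplaced reads at a small part of the identifiers could not have been seen and stay open. A gene model, a sequence or a gene content that differs between the cultivars stays open, as does a difference in expression, and none of these was tested.

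The 836 identifiers did not lie independently along the order of the identifiers. Those lower in 93-11 formed 32 neighbouring pairs, against a median of 14 and a highest value of 29 in 1000 random placements, and those lower in Nipponbare formed 25, against 8 and 19. The smaller ratio to the median was 2.286. The longest runs were LOC_Os12g34010 to LOC_Os12g34045, with 4 identifiers lower in Nipponbare, and LOC_Os08g42290 to LOC_Os08g42320, with 3 lower in 93-11. A candidate explanation is that single segments, missing from a genome or annotated differently, hold several of these genes, which would need the genome sequences to test.

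In 6 pairs the shares of cells were over 2-fold apart, with a median of 2.53-fold. To test whether cluster boundaries drawn differently were the cause, the cells of both libraries were assigned to the clusters of 1 library, and the median fold was then 2.024 on Nipponbare clusters and 2.44 on 93-11 clusters. Each median lay over the bound of 2 set beforehand. The median on Nipponbare clusters lies too close to that bound, given folds of 1.23 to 3.71 over the 6 pairs there, for the set as a whole to be decided. For 93-11 cluster 13 and Nipponbare cluster 16, 2.22-fold apart before, the smaller fold after assignment was 2.321 (1.89 to 2.87), with 99.7% and 100% of their cells assigned back to their own cluster and 100% and 96.2% to the partner. Of the 93-11 cells assigned to Nipponbare cluster 16, 89.4% came from cluster 13, and 93-11 cluster 20 also matched it best, but on that wider boundary the fold was 2.48, which argues against boundaries as the whole cause there. For the other 5 pairs boundaries and shares cannot be told apart, because the fold came under 1.5 or the assignment itself moved many cells: it was 3.714 after 4.87 for 93-11 cluster 16, 2.11 after 6.33 for cluster 19, 1.938 after 2.16 for cluster 15, 1.234 after 2.39 for cluster 9 and 0.6726 after 2.68 for cluster 8. Of the cells of 93-11 clusters 15 and 16, only 67.1% and 58.7% were assigned back to their own cluster, and of the 93-11 cells assigned to cluster 19 only 52.1% came from it, while dissection, wall digestion and cultivar stay open, untested, for all 6. Of the 8 pairs up to 2-fold apart, the order of shares turned on at least 1 assignment in 5 and on both in 2, 93-11 cluster 4 with Nipponbare cluster 11 and 93-11 cluster 12 with Nipponbare cluster 7.

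Identifiers next to each other in number, among those with at least 100 UMIs in the library, often led the same cluster. Among the 100 leading identifiers of each cluster there were 151 such neighbouring pairs in 93-11, against a highest value of 26 in 1000 random placements, and 99 in Nipponbare, against 23. The smaller of the ratios to the median of random placements was 9, so chance placement of leading identifiers was excluded as the source. Of the distinct neighbouring pairs, 133 in 93-11 and 92 in Nipponbare, 37 occurred in both. The longest run in both members of a pair of clusters was LOC_Os01g06990 to LOC_Os01g07060, with 5 identifiers, in 93-11 cluster 13 and Nipponbare cluster 16. Runs were formed among identifiers with at least 100 UMIs in each library. LOC_Os01g07010 and LOC_Os01g07020, which lie inside this run in number, had fewer in Nipponbare and were passed over. Neighbouring duplicate genes with a common pattern may underlie this, as may reads shared between such copies, and neither was tested.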
